A study of Arabidopsis thaliana with 8 samples.

How the data were processed

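Whole seedlings of wild-type and 35S:CAHB12 Arabidopsis were grown at 22 °C with 18 h light and 6 h dark, and RNA came from pools of 50 seedlings, with 4 µg used per library, per the labels. The labels call the 2 pools per group biological replicates. The submitters' processing notes name BWA 0.5.8c, Bowtie, edgeR and the genome build TAIR9. Which of these made which values is not given in the sources used here.

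The mRNA values used were raw counts per gene locus, per the file headers, which the values bear out as whole numbers with different totals, although the table is named for RPKM. The deposited table also gives CPM, computed by the authors from the reads in the table. The CPM reported here were computed from the counts with TMM factors. A transcript length per gene (other unit, bases) is given as deposited. A further 4 columns of RPKM for the same libraries were not used. The RPKM in the alternative fits and filters named below were computed from the counts and the transcript lengths. Each listed locus had at least 11 counts in at least 1 library. Of the 20701 loci, 20420 (98.64%) were in the name table, an annotation of a later build than TAIR9, so it served for names, neighbours and overlaps and no coordinates are given. The 10 most abundant loci took 11.86% and 11.8% of the counts in the wild-type replicates and 10.71% and 13.39% in the transgenic replicates. A count of 0 allows up to 0.1915 and 0.155 CPM in the wild-type replicates and 0.190 and 0.184 CPM in the transgenic replicates (3 counts per library, with TMM factors). Floors cover counting error only.

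The small RNA values, in another unit, RPM (reads scaled to the library total), were normalised by the authors. Their header says RPKM, but a single read was worth the same in every family of a column, so no length entered. Decimal marks had been lost for values of 1 and above, and runs of the same sample were already combined in 1 column. Each value was restored as the place of the decimal at which it is a whole number of reads and the samples of a family lie closest together. Of the 208 values, 163 were restored, and 100% were whole reads within 0.01 reads. Among values above 0, the highest of a restored family was at most 3.285 times the lowest, and the next wider placing gave at least 4.663 times. Moving the decimal mark of all samples of a family by the same number of places keeps that ratio. Of such equal placings the lowest was taken. The RPM levels, the filter on mean RPM and the ranking by abundance rest on that choice. On simulated data 59 of 60 families were fully recovered. The samples of a simulated family lay close together and no group difference was planted. The recovery of families that differ strongly between groups was thus not tested. The deposited log2 fold change, p and FDR (other units) of the authors' own comparison were used only where named.

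Because the values were counts, the test fixed for counts before the data were examined was used: edgeR 4.0.16 in R 4.3.3, with TMM, filterByExpr, glmQLFit and glmQLFTest, no covariate, and Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.103. Counts of replicates differed more than reads alone would give (chi-square per degree of freedom 10.15 for the wild-type pair and 11.04 for the transgenic pair). The SE of a log2 fold change is its size over the root of the F statistic. Principal components were computed on log2 CPM with a prior of 2, and the first and second held 49.15% and 30.11% of the variance. Gene lists were tested with camera (limma 3.58.1, correlation 0.01, two-sided) where at least 3 members were tested, and with fry and an estimated correlation. The lists were those named in the report, and each gene of a list was matched by locus. Small RNA was tested by limma on log2(RPM + 1) for families with a mean of at least 5 RPM. The relation to targets used 100000 permutations.

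Genes were named by a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, filled by the smallest p, up to 4 members of each list by the smallest p, and a fixed set of ABA, gibberellin and HD-Zip genes. For small RNA it took up to 4 families per direction and the 5 most abundant. Alternatives were limma on log2 RPKM with pseudocounts of 0.5, 0.1 and 1 and with quantile normalization, other filters, no variance trend, robust fitting, a replicate block, each library left out, DESeq2 1.42.0, and adjusted p under 0.1. Further alternatives, chosen after seeing the data, were RLE factors and no normalization factors in edgeR, and edgeR on the recovered small RNA reads with and without a replicate block. With 1 library left out, the lone library of a group is assumed to vary like the others. Figures used Python 3.11.15 and matplotlib 3.10.9. On simulated data with 200 of 20168 genes planted, edgeR recovered 23.88% at 1.5-fold, 85.07% at 2-fold and 96.97% at 4-fold, and called 7 unplanted genes. The planted genes all had a mean above 1 CPM. Libraries were drawn independently, so differences shared by replicates of the same number were not simulated.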

Results

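Messenger RNA and small RNA were profiled in whole 10 day old seedlings of Arabidopsis thaliana, accession Columbia, either wild type or carrying the coffee gene CAHB12 behind the constitutive 35S promoter. CAHB12 encodes a homeodomain-leucine zipper protein of class I, a plant transcription factor family with members that respond to drought and to the hormone abscisic acid (ABA). Each library came from a pool of 50 seedlings. There were 2 wild-type and 2 transgenic pools for each RNA type, which the labels call biological replicates. The design text mentions a pair of transgenic lines, but the sample labels do not tie a replicate to a line. The mRNA table listed 20701 gene loci, with total counts of 15682546 and 19436632 in the wild-type replicates and 15424261 and 16615556 in the transgenic replicates. The small RNA table listed 52 microRNA families, and the value of a single read in each column implied libraries of 16715396 and 9463330 reads (wild type) and 7638192 and 6975406 reads (transgenic).

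The first comparison asked which transcripts differed between transgenic and wild-type seedlings. In transgenic seedlings 3 genes of the thalianol cluster, which makes a root triterpene, rose. The thalianol synthase gene THAS1 (AT5G48010) went from 10.6 ± 0.449 CPM (SD, n = 2) to 55.9 ± 1.86 CPM (SD, n = 2), 5.26-fold higher by edgeR (adjusted p = 0.000138). Its neighbours CYP708A2 (AT5G48000, thalianol hydroxylase) and CYP705A5 (AT5G47990, thalian-diol desaturase) rose 5.19-fold and 7.08-fold. CYP71A16 (AT5G42590), the marneral oxidase gene of a related cluster, rose 4.43-fold, from 1.48 ± 0.104 to 6.59 ± 1.18 CPM (SD, n = 2; edgeR adjusted p = 0.0287). The thalianol cluster was singled out after its values were seen, and its members AT5G47980 and AT5G47950 did not pass, with log2 fold changes of 0.60 and -0.24 (edgeR adjusted p = 0.681 and 0.821). The root markers fixed for this tissue had a median log2 fold change of 0.09 over 8 genes and did not pass the list test.

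In all, 20298 genes were tested by edgeR's quasi-likelihood test, and 7 rose and 10 fell at a Benjamini-Hochberg adjusted p under 0.05. An unadjusted p under 0.05 was reached by 1608 genes. The other genes that rose were AT3G60920 (0.534 ± 0.123 to 14.1 ± 0.116 CPM, SD, n = 2), the cation/proton exchanger gene CHX17 (AT4G23700; log2 fold change 2.58, SE 0.15) and the jacalin lectin gene JAL22 (AT2G39310; 2.43-fold). Among the genes that fell, EARLI1 (AT4G12480), a lipid transfer-type protein gene, went from 86.1 ± 17.38 to 10.6 ± 0.221 CPM (SD, n = 2). The sulfur-deficiency gene SDI1 (AT5G48850, ATSDI1 in the name table) was 3.62-fold lower, the calmodulin-like gene TCH3 (AT2G41100) 2.098-fold and the cytochrome P450 gene CYP702A5 (AT4G15393) 2.82-fold lower. AT1G05700, AT5G03350 and AT3G54040 were 2.965-fold, 2.74-fold and 2.28-fold lower.

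Transcripts of MRD1 (AT1G53480) and AT3G14670 were not counted in either transgenic library. MRD1 had 100 and 143 counts in the wild-type replicates, and AT3G14670 had 41 and 55. Against a floor of 3 counts over the transgenic group, MRD1 was at least 74.3-fold lower and AT3G14670 at least 29.4-fold lower. HEI10 (AT1G53490) also passed the test, with 117 and 160 counts in wild type and 21 and 29 in transgenic seedlings. Its gene model overlaps that of MRD1, and subtracting the MRD1 counts left 17 and 17 counts in wild type against 21 and 29, so a fall of HEI10 itself is uncertain. The gene models of AT3G60920, AT5G03350, AT3G54040, TCH3 and EARLI1 also overlap other annotated genes, with which reads can be shared.

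**Figure D1:**
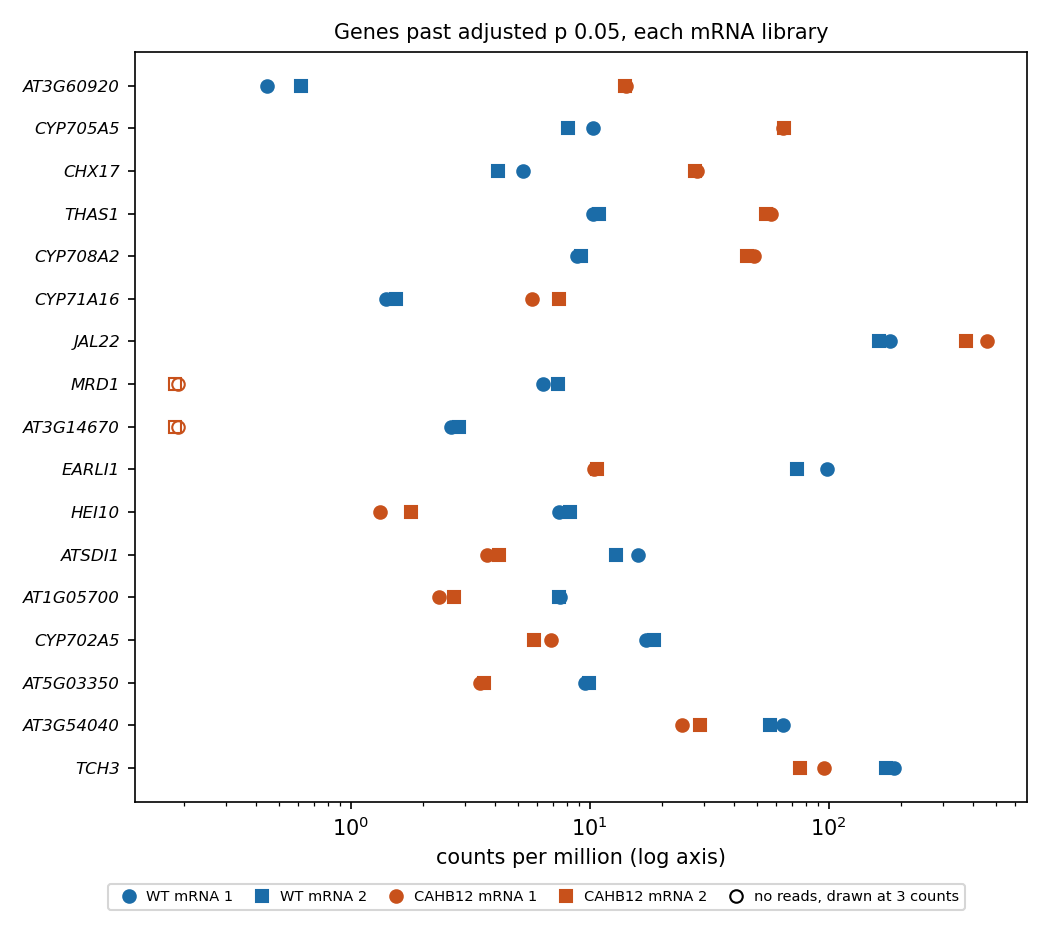
CPM on a log axis for the 17 genes past adjusted p 0.05, with 1 point per mRNA library (blue, wild type; orange, 35S:CAHB12; circles, replicate 1; squares, replicate 2). Open symbols are libraries with no reads, drawn at 3 counts per library; both transgenic points lie on 1 side of both wild-type points in 17 of the 17 genes.

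The groups did not overlap for 17 of these 17 genes. Among all genes tested they did not overlap for 39.45%, where chance alone gives 33.33%. DESeq2 called 76 genes, 29 higher and 47 lower, with 17 of the 17 among them, whereas limma on log2 RPKM called 8 or 9 genes, 8 of them shared, and robust fitting in edgeR called 31. Of the 17 calls, 11 were kept with any 1 library left out, and CYP71A16, AT1G05700, CYP702A5, AT5G03350, AT3G54040 and TCH3 each lost theirs in at least 1 such fit, always one that left out a transgenic replicate. The total went to 411 without wild-type replicate 2, 72 without wild-type replicate 1, 24 without transgenic replicate 1 and 16 without transgenic replicate 2. The next genes, which did not pass, were AT2G05540 (1.96-fold higher), the small heat shock gene HSP17.6II (AT5G12020; 2.92-fold higher) and AT4G07820 (1.99-fold higher), each at edgeR adjusted p = 0.0601. All 3 passed with either 1 of the wild-type replicates left out.

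The second comparison asked whether groups of genes fixed before the data were examined moved together. Heat shock genes were higher as a list, and flavonoid, jasmonate, ABA response, salicylic acid and light harvesting genes were lower. Of the 18 lists, 17 had at least 3 tested members and 6 passed camera with a preset correlation of 0.01 (Benjamini-Hochberg adjusted p under 0.05 over the lists). None of these calls held with an estimated correlation, where 0 of the 17 lists passed and 0 had an unadjusted p under 0.05. No member of a list passed the test over all genes.

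Heat shock genes were higher (camera adjusted p = 4.66e-28; adjusted p = 0.464 with an estimated correlation). Their median log2 fold change was 0.67, the 17 tested members had higher means in transgenic seedlings, 0 rose over all genes tested and 13 rose adjusted over the list alone. HSP17.6II went from 2.33 ± 0.225 to 6.79 ± 0.405 CPM (SD, n = 2), and HSP17.6A (AT5G12030), also a small heat shock protein gene, from 6.87 ± 1.04 to 17.9 ± 4.91 CPM (SD, n = 2). The log2 fold change of HSP17.6A ranged from 1.05 (without transgenic replicate 1) to 1.63 (without transgenic replicate 2), and it passed with any 1 library other than transgenic replicate 1 left out.

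ABA and dehydration response genes were lower as a list (camera adjusted p = 6.16e-07; adjusted p = 0.574 with an estimated correlation), with a median log2 fold change of -0.31 over 32 genes. Adjusted over the list alone, 8 fell and 1 rose, and over all genes tested 0 passed. The lipid transfer protein gene LTP4 (AT5G59310) had 32.6 ± 7.33 CPM in wild type and 17.9 ± 1.83 CPM in transgenic seedlings (SD, n = 2), and the cold-regulated gene COR15A (AT2G42540) had 647 ± 27 and 461 ± 33.0 CPM. The ABA-responsive genes RD29A (AT5G52310), RD29B (AT5G52300) and RAB18 (AT5G66400) had log2 fold changes of -0.87, 0.04 and -0.33. NCED3 (AT3G14440), an ABA synthesis enzyme gene, had -0.43. With 1 library left out, RD29A ranged from -1.38 (without transgenic replicate 1) to -0.31 (without wild-type replicate 1), and NCED3 from -0.88 (without transgenic replicate 1) to -0.098 (without transgenic replicate 2). The ranges were -0.038 to 0.105 for RD29B, -0.45 to -0.22 for RAB18 and -1.075 to -0.62 for LTP4. RD29A passed without wild-type replicate 2 and LTP4 without wild-type replicate 1. RD29A stood at 386 and 199 CPM in the wild-type replicates and 207 and 113 CPM in the transgenic replicates.

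The list of ABA receptors, clade A PP2C phosphatases and SnRK2 kinases had camera adjusted p = 0.0536 over 19 genes, and 0.0125 without wild-type replicate 1. The receptor gene PYL6 (AT2G40330) had a log2 fold change of -1.91 and PYL8 (AT5G53160) 0.39. PYL5, ABI1, ABI2 and HAI1 had -0.26, -0.38, -0.11 and -0.20. Without wild-type replicate 2, ABI1 passed at -0.67 and HAI1 had -0.33, and without wild-type replicate 1 they had -0.041 and -0.074. Leaving out 1 library gave ranges of -2.81 to -1.375 for PYL6, 0.21 to 0.58 for PYL8, -0.60 to 0.20 for PYL5 and -0.47 to 0.18 for ABI2. Neither the HD-Zip class I list (camera adjusted p = 0.786, 14 genes) nor gibberellin metabolism and signalling (camera adjusted p = 0.786, 15 genes) passed. HB7 (AT2G46680), HB12 (AT3G61890) and GA20OX1 (AT4G25420) had log2 fold changes of -0.32, -0.22 and -0.17, HB1 -0.13, RGL2 0.39 and RGL1 0.27. Leaving out 1 library, HB7 ranged from -0.68 (without transgenic replicate 1) to -0.001374 (without wild-type replicate 1), HB12 from -0.37 to -0.092, GA20OX1 from -0.76 to 0.67, HB1 from -0.17 to -0.10 and RGL2 from 0.27 to 0.48. The table lists no coffee gene, so the transgene itself was not measured here.

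Flavonoid and anthocyanin synthesis genes were lower (camera adjusted p = 1.18e-09; adjusted p = 0.464 with an estimated correlation). Their median log2 fold change was -0.48, 10 of 10 members had lower means, and 4 fell adjusted over the list alone, against 0 over all genes tested. DFR (AT5G42800), a dihydroflavonol reductase gene, had 5.06 ± 0.791 and 2.31 ± 0.136 CPM (SD, n = 2), and the glycosyltransferase gene UF3GT (AT5G54060) 2.07 ± 0.509 and 0.433 ± 0.255 CPM (SD, n = 2). Their log2 fold changes ranged from -1.29 to -0.96 and from -2.98 to -1.735 with 1 library left out, and both genes passed without wild-type replicate 2.

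Jasmonate response genes were lower too (camera adjusted p = 6.16e-07; adjusted p = 0.464 with an estimated correlation), with lower means in 8 of 8 members and 2 that fell adjusted over the list alone, against 0 over all genes tested. The vegetative storage protein gene VSP2 (AT5G24770) had a log2 fold change of -0.67 and JAZ5 (AT1G17380) of -1.27, and VSP2 passed with either 1 of the wild-type replicates left out (range -0.82 to -0.54 with 1 library left out). Salicylic acid and pathogen defence genes were lower (camera adjusted p = 0.00127; adjusted p = 0.464 with an estimated correlation), with 1 of 10 that fell adjusted over the list alone and 0 over all genes tested. PR2 (AT3G57260), with 10 and 45 counts in wild type and 3 and 3 in transgenic seedlings, had a log2 fold change of -2.99, which was -3.59 without wild-type replicate 1, where it passed, and -1.74 without wild-type replicate 2. WRKY70 (AT3G56400) stood at 67.6 and 22.35 CPM in the wild-type replicates and 21.3 and 10.9 CPM in the transgenic replicates. Its log2 fold change ranged from -2.08 (without wild-type replicate 2, where it passed) to -0.48 (without wild-type replicate 1). On the first principal component the wild-type replicates lay at -32.5 and -3.67 and the transgenic replicates at 9.37 and 26.8. On the second component they lay at -0.674 and 16.9 (wild type) and at -27.24 and 11.01 (transgenic). Wild-type replicate 1 was thus farthest out on the first component and transgenic replicate 1 on the second. In both genotypes replicate 2 lay above replicate 1 on both components.

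Light harvesting and Rubisco genes were lower (camera adjusted p = 0.0018; adjusted p = 0.728 with an estimated correlation), with a median log2 fold change of -0.12 over 25 genes and 0 past the test over all genes or adjusted over the list alone. LHCB1.1 (AT1G29920) and LHCB2.1 (AT2G05100) had -0.44 and -0.58, with ranges of -0.61 to -0.25 and -0.89 to -0.26 with 1 library left out. LHCB2.1 passed without wild-type replicate 2. Without wild-type replicate 1, where both were nearest 0, the list had camera adjusted p = 0.308.

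The other lists did not pass. Oxidative stress and antioxidant enzymes had camera adjusted p = 0.851, and 4 rose and 2 fell adjusted over the list alone. The superoxide dismutase genes CSD2 (AT2G28190) and CSD1 (AT1G08830) had log2 fold changes of 0.95 and 0.59, and CSD2 passed with either 1 of the wild-type replicates left out. Expansins and xyloglucan endotransglucosylases had camera adjusted p = 0.465 (EXPA4 -0.32, XTH23 -0.57) and auxin response 0.636 (GH3.3 -0.24, IAA19 -0.35). Glucosinolate synthesis had 0.0735 (MAM1 -0.25, SUR1 -0.37), circadian clock genes 0.208 (CCA1 -0.86, PRR5 -0.23) and senescence markers 0.191 (SAG21 0.50, SEN1 0.66), where 1 of 5 rose adjusted over the list alone. With an estimated correlation these 3 lists had camera adjusted p of 0.801, 0.728 and 0.574. The direction of the glucosinolate list turned without wild-type replicate 1. Over fits with 1 library left out the log2 fold change ranged from -0.43 to -0.22 for EXPA4, -0.70 to -0.44 for XTH23, -0.32 to -0.185 for MAM1, -0.30 to -0.15 for PRR5 and 0.39 to 0.61 for SAG21. SEN1 ranged from 0.16 (without transgenic replicate 2) to 1.21 (without wild-type replicate 2). CCA1 and SUR1 ranged from -1.23 and -0.60 (without wild-type replicate 2) to -0.42 and -0.11 (without wild-type replicate 1). SUR1, SAG21 and SEN1 passed without wild-type replicate 2.

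Root markers had camera adjusted p = 0.976 (PYK10 0.30, NRT2.1 -0.65, with ranges of 0.22 to 0.37 and -0.82 to -0.505 with 1 library left out), with a median of 0.09 and a mean of -0.06. In the oxidative stress list the median and the mean were below 0 (-0.06 and -0.002355), while the test pointed up. Seed storage and oil body markers (4 tested, camera adjusted p = 0.976) had a median of 0.74 and a mean of 0.81 while the test pointed down. Their levels differed between the transgenic replicates, from 0.126 to 54.7 CPM for CRC (AT4G28520) and from 0.506 to 5.95 CPM for OLEO1. That list passed as higher without transgenic replicate 1 (camera adjusted p = 1.73e-12) and as lower without transgenic replicate 2 (camera adjusted p = 9.76e-21). Only SEP3 of the floral organ markers was tested, at -0.75 (-1.61 to 0.94 with 1 library left out), so that list was not.

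**Figure D2:**
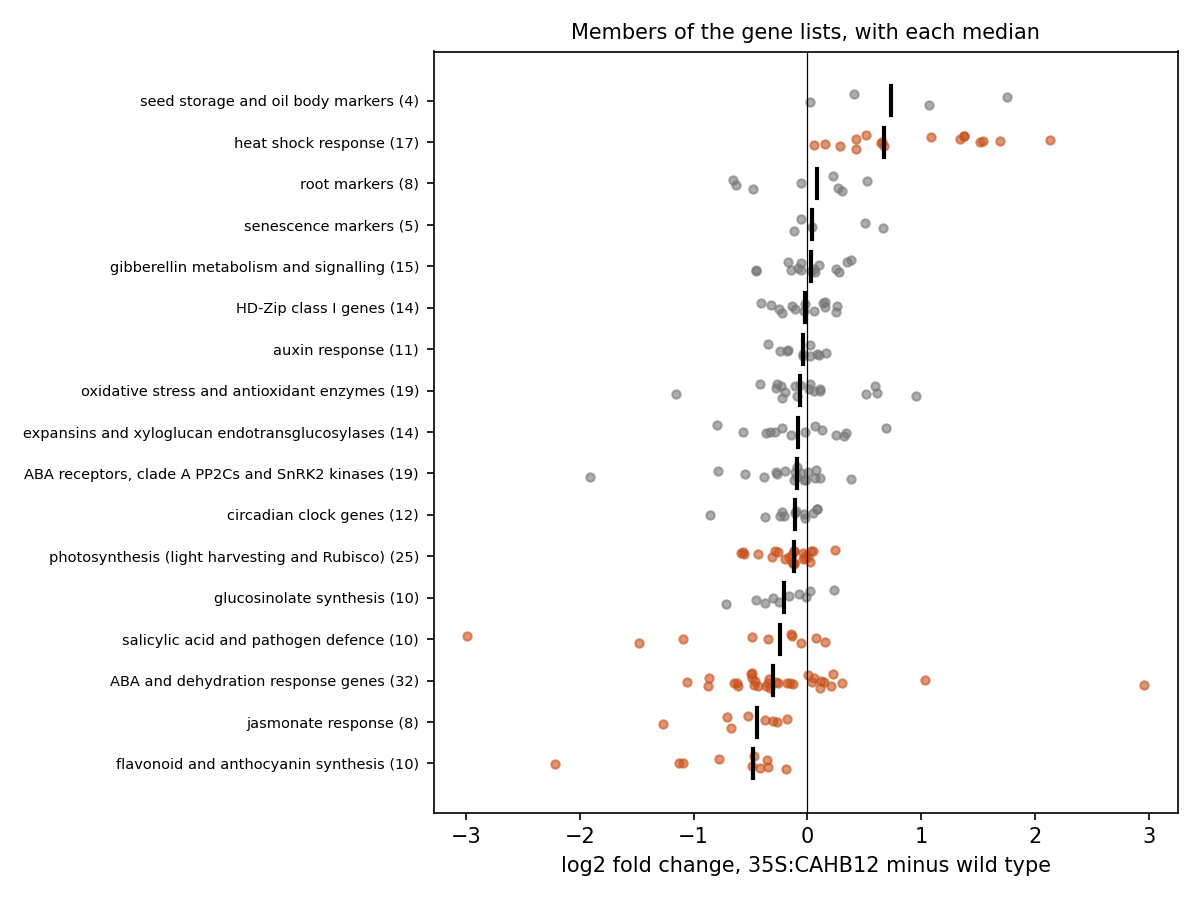
Log2 fold change (35S:CAHB12 minus wild type, horizontal axis) of each tested member of the 17 lists, with the number of members in brackets and a bar at each median. Orange lists passed camera with a preset correlation; heat shock members lie at a median of 0.67 and flavonoid and anthocyanin members at -0.48.

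The third comparison asked whether microRNA families differed. No family passed in the fit fixed for this comparison. Of the 29 families with a mean of at least 5 RPM, 0 passed limma's moderated test on log2(RPM + 1) and 0 had an unadjusted p under 0.05. edgeR on the recovered reads also called 0, with 2 at an unadjusted p under 0.05. The lowest p belonged to MIR5653, at 16.5 ± 0.296 RPM in wild type and 10.7 ± 1.66 RPM in transgenic seedlings (SD, n = 2; limma adjusted p = 0.972). MIR841 had 28.8 ± 2.999 and 19.4 ± 1.95 RPM, MIR5643 28.3 ± 6.92 and 19.1 ± 3.55 RPM, and MIR169_1 6.265 ± 0.193 and 4.81 ± 0.696 RPM. MIR399 was the 1 tested family with both transgenic samples above both wild-type samples, at 46.65 ± 4.72 and 52.2 ± 1.61 RPM. The 5 most abundant families were MIR166, MIR168, MIR159, MIR167_1 and MIR161, with log2 fold changes of -0.14, -0.16, -0.19, 0.05 and 0.05. The pseudocount makes fold changes of rare families smaller, and the SE of 0.36 was shared by all families. The fit had no term for replicate number, although 11 of the 29 families differed between replicates 2 and 1 (limma adjusted p under 0.05). Such differences enter that SE, so this result does not show that the families were unchanged. Fits with a replicate block are given with the other processing choices.

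The authors' deposited table gives its own fold changes and FDR for these families, with groups that its header does not name. An FDR under 0.05 was given for 12 families in the authors' deposited table, 11 higher and 1 lower (MIR395). An edgeR exact test of the replicate 2 samples against the replicate 1 samples, on the recovered reads, gave log2 fold changes within 0.01 of those in the authors' deposited table for 52 of 52 families. The same test of transgenic against wild-type samples gave a difference of up to 2.27 from the authors' deposited table, with 0 families past FDR 0.05 and 0 at an unadjusted p under 0.05. MIR773, which had the lowest FDR in the authors' deposited table, stood at 54.3 and 148.5 RPM in wild-type replicates 1 and 2 and at 63.2 and 135.6 RPM in transgenic replicates 1 and 2.

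**Figure D3:**
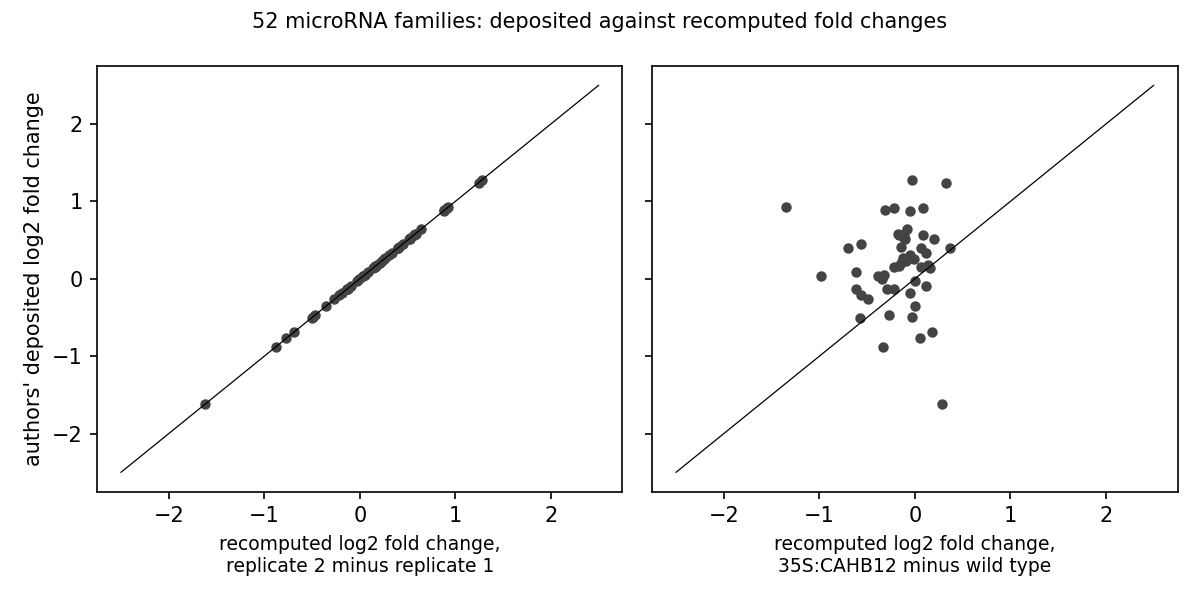
Log2 fold changes of 52 microRNA families in the authors' deposited table (vertical axis) against those recomputed from recovered reads (horizontal axis), as replicate 2 minus replicate 1 (left) and as 35S:CAHB12 minus wild type (right). Points on the line are equal; 52 of 52 lie within 0.01 of it on the left and 0 of 52 on the right.

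The last comparison set each microRNA family beside its known targets. Targets of miR398, the superoxide dismutase genes CSD1 and CSD2 and their copper chaperone gene CCS1, were higher as a list (camera adjusted p = 1.15e-09; adjusted p = 0.557 with an estimated correlation). Their mean log2 fold change was 0.68, and 3 of 3 rose adjusted over the list alone, against 0 over all genes tested. The miR398 family itself had a log2 fold change of 0.14. No other family with 3 or more tested targets passed. Across 17 families, which are not independent replicates, the microRNA and mean target changes had Pearson's r = 0.507 (two-sided permutation p = 0.0297) and Spearman's rho = 0.397 (permutation p = 0.115). With the relation of the fold changes in the authors' deposited table to the target changes, 2 relations were computed, and adjusted over both p was 0.0595 for r and 0.231 for rho. Without the 2 families farthest from the median r was 0.193 (permutation p = 0.489), so the relation rests on those families.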

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

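The tests of the replicate contrast and of the decimal marks were chosen only after the result was seen. The authors' deposited table of small RNA fold changes has 12 families with an FDR under 0.05, and it stands outside the comparisons made on the library values. An exact test of replicate 2 against replicate 1 gave log2 fold changes that differed from the deposited ones by at most 0.008105, so a candidate explanation is that the deposited comparison sets the columns of replicate 2 against those of replicate 1. The 5 families with no value restored differed from that contrast by at most 7.745e-07. For those families this argues against an error in restoring the decimal marks as the source. They lay under 1 RPM in every sample and were not among the 12 with an FDR under 0.05. They cannot by themselves show that the values of the 47 restored families are right. In that contrast all 52 families lay within 0.01 of the deposited log2 fold changes, which argues against a mark misplaced in a single sample. A mark moved alike in all samples of a family would keep its fold change, so the RPM levels stay unchecked. Exchanged labels of wild-type replicate 2 and transgenic replicate 1 stay open: the deposited fold changes and the target changes had r = 0.0371 across 17 families (permutation p = 0.872), which decides nothing. No biological explanation was tested.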

How the results depend on the processing

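The alternatives on RLE factors, no normalization factors and recovered reads were chosen only after the results were seen. Depth limits genes with few counts, and the cause was not tested where a value moved unless the setting itself removes genes or libraries. Genes called numbered 9, 8, 9 and 9 with limma on log2 RPKM (pseudocounts 0.5, 0.1 and 1, and quantile normalization), with 8 shared in each. They numbered 9 with the stricter RPKM filter, which tested 12196 genes, 31 with robust fitting, 596 with a replicate block (227 higher, 369 lower), 76 with DESeq2 and 41 at adjusted p under 0.1, and 16 to 411 with 1 library left out. They numbered 17 with RLE factors and 18 without factors. Of the values of 64 genes named in the report, 11 reversed over all alternatives, none past a threshold: CRC had -0.40 with a pseudocount of 0.1, and with 1 library left out the ranges were -0.76 to 0.67 for GA20OX1, -0.47 to 0.18 for ABI2, -1.61 to 0.94 for SEP3, -0.038 to 0.105 for RD29B, -0.60 to 0.20 for PYL5, -5.92 to 3.65 for CRC and -1.60 to 1.93 for OLEO1. The others of these 64 genes kept their direction in the settings run for them. Over all settings 860 gene values stayed on their side of the threshold in the same direction, 65 gained a call and 49 lost one.

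With an estimated correlation 0 of the 17 lists passed (adjusted p 0.574 for ABA and dehydration response, 0.728 for photosynthesis, and 0.464 for each of heat shock, salicylic acid, jasmonate and flavonoid genes). With fry 1 passed, the ABA receptors, phosphatases and kinases (0.00549), which also passed with no variance trend (0.0447). The lists called by camera had fry adjusted p of 0.476 for ABA and dehydration response, 0.503 for photosynthesis, and 0.388 for each of heat shock, salicylic acid, jasmonate and flavonoid genes. With limma the salicylic acid list had 0.0509 (pseudocount 0.5), 0.0615 (0.1) and 0.0639 (quantile), and photosynthesis 0.0639 (quantile). The direction of the oxidative stress list turned with limma (0.701, 0.704, 0.724 and 0.872 for pseudocounts 0.5, 0.1 and 1 and quantile), and that of the root markers with limma (0.491, 0.519, 0.454 and 0.574), a replicate block (0.516) and fry (0.993). A replicate block added glucosinolate synthesis (0.00116) and senescence markers (0.00367).

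With 1 library left out, 6 to 10 lists passed, and the adjusted p ranged from 0.0125 to 0.156 for the ABA receptor list, 0.485 to 0.964 for HD-Zip class I, 0.432 to 0.898 for gibberellin, 0.352 to 0.868 for oxidative stress, 1.13e-05 to 0.308 for photosynthesis, 0.4365 to 0.882 for auxin, 1.06e-07 to 0.597 for glucosinolate, 0.485 to 0.883 for root markers, 9.76e-21 to 0.822 for seed storage, 0.0321 to 0.562 for senescence and 0.0141 to 0.868 for the clock. The direction turned in at least 1 of these fits for HD-Zip class I, gibberellin, oxidative stress, auxin, glucosinolate, root and seed storage lists.

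For small RNA 3 families, MIR5653, MIR841 and MIR5643, passed as lower with a replicate block in limma (adjusted p = 0.0101 each) and 0 in the other settings, edgeR with a replicate block included. Between replicates 2 and 1 of both genotypes, 11 of the 29 families differed at adjusted p under 0.05 in limma. In both genotypes the small RNA column of replicate 1 names 1 sequencing run and that of replicate 2 names 2 combined runs. Replicate number and number of runs thus cannot be told apart there. The labels do not say what else a replicate number shares. The differences in log2 CPM between replicates 1 and 2 of the wild-type and of the transgenic mRNA libraries had a correlation of 0.228 across the tested genes. The log2 fold change with 1 sample left out ranged from -0.50 to 0.21 for MIR166, -0.53 to 0.14 for MIR159, -0.21 to 0.30 for MIR167_1 and -0.15 to 0.26 for MIR161. The correlation with targets was 0.193 without the 2 farthest families. The fits on the first or the second sequencing run alone were not run, since the runs were already combined, and TMM-like scaling of the mRNA RPKM was not run, since TMM was used on the counts.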

Other observations

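The tests of root tissue, single libraries, neighbouring genes, overlapping gene models and the low sulfate list were chosen only after the results were seen. Genes that respond to low sulfate had lower means in transgenic seedlings. LSU1 (AT3G49580) had 11.8 ± 2.64 CPM in wild type and 5.495 ± 1.44 CPM in transgenic seedlings (SD, n = 2), APR3 (AT4G21990), an adenylyl-sulfate reductase gene, 249 ± 52.7 and 138 ± 24.0 CPM, and SHM7 (AT1G36370) 154 ± 15.7 and 78.1 ± 16.5 CPM. None of these passed edgeR's test over all genes (adjusted p = 0.256, 0.217 and 0.0969), whereas SDI1 did. Over the 13 tested members of the list without SDI1 the median log2 fold change was -0.77, and 12 were lower. That median was -0.47 without wild-type replicate 1, -1.07 without wild-type replicate 2, -1.125 without transgenic replicate 1 and -0.54 without transgenic replicate 2. That the list may be lower together was not decided: fry gave p = 0.1065, camera with an estimated correlation p = 0.0508, and without the 2 members seen before the list was written fry gave p = 0.134 over 11 genes, 10 of them lower.

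The marneral cluster beside CYP71A16 showed higher means too. CYP705A12 (AT5G42580) had 0.367 ± 0.0669 and 1.70 ± 0.801 CPM (SD, n = 2; edgeR adjusted p = 0.298), and the marneral synthase gene MRN1 (AT5G42600) 0.0259 ± 0.0366 and 1.43 ± 0.235 CPM (SD, n = 2; edgeR adjusted p = 0.0679). Of 8 thalianol and marneral genes, 7 had higher means and the median log2 fold change was 2.28, on genes chosen after their values were seen. A larger share of root tissue may be set aside as the whole cause, since the 8 root markers had a median of 0.08755 with an SD of 0.465. With 1 library left out the lowest cluster median was 2.19, so no single library made this rise. Genes singled out for calls with both groups apart were bound to give such a result, so it adds no further support. Other changes in which tissues express the cluster stay open.

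Some called genes lay next to each other. The 17 genes held 3 neighbouring pairs, of which 1 was MRD1 and HEI10. Without HEI10, 16 genes held 2 pairs, both of thalianol genes, and 1 of 10000 draws of as many tested genes held as many (permutation p = 2e-04). Both pairs belong to 1 run of genes in a known cluster, which was seen before the test. The draws treat genes as unrelated, so this p adds nothing beyond the cluster itself. For MRD1 and HEI10 shared reads are a candidate source, since the ratio of wild type to transgenic CPM of HEI10 less MRD1 was 0.624. For the thalianol pairs 0 gene models overlapped in the name table, which argues against shared reads from overlapping models. That annotation is of a later build than TAIR9, so overlaps in the models used for counting were not checked. Beside EARLI1, AZI1 (AT4G12470) had a log2 fold change of -2.14 (edgeR adjusted p = 0.0969). On its other side AT4G12490 had -5.73 (edgeR adjusted p = 0.0989), so neither neighbour passed.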
